A study of Drosophila melanogaster with 9 samples.

How the data were processed

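Transcript levels were measured on Affymetrix Drosophila Genome 2.0 arrays in the head and thorax of female Canton-S flies, a standard laboratory wild-type strain, at 10 days of age. The 9 arrays covered 3 diets with 3 biological replicates each: a normal diet, a restricted diet, and the normal diet with added resveratrol, a plant polyphenol. Per the labels, the RNA for each array came from a pool of 75 or more flies, was extracted with Trizol and cleaned on columns, and 5 µg entered a single-cycle labelling reaction. The make-up of the diets and the dose of resveratrol are not given in the sources used here.

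The deposited values are log2 probe set summaries, which the authors made with GCRMA according to the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, normalizes the arrays to a common distribution and summarises the probes of each set. Its version and the set of arrays normalized together are not given in the sources used here. The log2 scale was read from the values, which ran from 2.12 to 16.39 with none missing. Between 33.3% and 34.9% of the probe sets of an array stood exactly at the lowest value, and between 49.5% and 50.1% reached log2 4. Background subtraction of this kind widens fold changes near the floor, and values near log2 16.3 sit at a ceiling, where no change is read. Where the mean of the lower group lay under log2 4, a fold is therefore given as a lower bound, computed from the brighter group's mean against log2 4. For Jon44E and CG11912 a normal-diet array lay above log2 4, so their figures are not strict lower bounds. For arrays, the number of replicates limits the precision; there is no count of molecules behind a value.

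The table held 18952 probe sets. The 183 control probe sets were left out of the tests. Of the other 18769, 13646 named 1 gene, 402 named several and 4721 named none in the platform annotation used here. Symbols came from that annotation and were looked up by gene identifier in the gene table of the fly assembly Release 6 plus ISO1 MT, which held 13543 of the 13646. No genome build was used, and no coordinates are given. A probe set entered the tests where at least 3 of the 9 arrays reached log2 4, which 9401 did. Of several probe sets naming the same gene, the probe set with the highest mean over all arrays stood for it. This left 8822 features, called genes below: 7759 named 1 gene, 234 named several and 829 named none.

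All 9 arrays were fitted together in limma 3.58.1 under R 4.3.3 with a mean per diet and empirical Bayes moderation, with neither the trend nor the robust option. The spread had 6 residual degrees of freedom, and the prior added 1.81. The comparisons were restricted diet minus normal diet, resveratrol minus normal diet, and restricted diet minus resveratrol. A gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no minimum fold. Adjusted p values of single genes are limma's throughout. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 36 of 37 lists with at least 3 measured members. The list of male reproductive genes had 1 measured member and was not tested. The same test with an estimated correlation, and limma's fry, were run beside it; fry asks whether a list's genes move 1 way on balance and does not compare them with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

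The lists, the tests, the rule for named genes and most alternatives were set before the data were examined. Named genes were the 12 largest changes each way for each treatment against the normal diet, and the 6 largest each way for restricted diet against resveratrol. They had to pass the threshold with the 3 values of a group all on the same side of the 3 of the other. Up to 4 members with the smallest p were named from each called list and from the lists of yolk proteins, insulin, TOR and FOXO genes, sirtuin, p53 and AMPK genes, and takeout and juvenile hormone genes. Up to 10 genes changed by both treatments, and Sirt1, p53, foxo, Yp1, Yp2 and Yp3, were also named. The rule also held the genes to, Thor and Ilp6, which are not analysed here. Genes named outside the rule are said to be chosen after their values were seen. No named gene had another probe set past the threshold in the opposite direction.

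For genes changed by both treatments, the shared normal-diet arrays were allowed for by 100 simulated sets of unchanged groups drawn from the fit's residuals, and, after seeing the data, by giving 1 normal-diet array to a treatment and the other 2 to the other, in all 6 ways. Alternatives covered the normalization between arrays, the filter, the probe set standing for a gene, the variance model, the test, the threshold, the arrays in the fit, a term for the replicate number and leaving out each array. RNA quality was read from the differences between 3' and 5' control probe sets, with exact permutation tests. A covariate for germline transcripts, and marker lists for midgut, antenna, germline and eggshell, were added after seeing the data.

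The pipeline was tested on simulated data of the same size in which 67, 67 and 66 genes per comparison were given a known log2 change of 0.5, 1 and 2. For restricted diet against normal diet it recovered 62.7%, 97.0% and 97.0% of them, with 10 false calls among 8822 genes. For resveratrol against normal diet the shares were 62.7%, 88.1% and 93.9% with 7 false calls, and for restricted diet against resveratrol 65.7%, 92.5% and 93.9% with 6. In the simulated comparison of restricted diet with normal diet, the list test called a list of 25 genes moved by 0.3 and none of 20 unmoved lists. The simulated genes were drawn independently of each other and the lists at random. The check therefore cannot show how often camera calls unmoved lists whose genes vary together. Estimated correlations of the real lists reached 0.79, for DNA replication genes. Gene tables were prepared with Python 3.11.15 and pandas 2.3.3, R read its tables with data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9.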

Results

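Transcript levels were compared between female Canton-S flies, 10 days old, kept on a normal diet, on a restricted diet, or on the normal diet with resveratrol. Each diet had 3 biological replicates, and each replicate was a pool of head and thorax RNA. Dietary restriction and resveratrol have both been studied as ways to lengthen life, and the series set their effects on transcripts side by side. On each array between 9295 and 9405 of the 18769 probe sets that were not controls reached log2 4, and 8822 genes were tested. Values are log2 units unless a fold is stated.

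Arrays of the same diet correlated at 0.973 to 0.991 across probe sets, and arrays of different diets at 0.932 to 0.990. The first principal component carried 55% of the variance. The restricted-diet arrays lay from 20.99 to 34.34 on it, the resveratrol arrays from -17.4 to 15.25 and the normal-diet arrays from -47.11 to -6.79. The second component carried 16.5%.

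The restricted diet was set against the normal diet to ask which transcripts differ when the diet is restricted. Many digestive enzyme transcripts were far higher on the restricted diet, and most listed neuron and photoreceptor genes and some muscle genes were modestly lower. Jon25Biii (CG8871), a serine protease of the Jonah family, rose from 7.23 ± 2.72 to 13.79 ± 0.82 (SD, n = 3), 94.8-fold, or 42.6-fold without normal-diet replicate 2 and 268-fold without normal-diet replicate 3. Lsp2 (CG6806), a larval serum protein made by the fat body, rose 14.9-fold, from 10.21 ± 0.55 to 14.11 ± 0.38. nSyb, a synaptic vesicle protein, fell by 0.80, from 10.11 ± 0.19 to 9.31 ± 0.05, and inaC, the eye's protein kinase C, fell by 0.71, from 10.51 ± 0.13 to 9.80 ± 0.03. In all, 1604 of 8822 genes passed in limma, 465 higher and 1139 lower on the restricted diet. Of these, 152 changed at least 2-fold, 132 of them higher. At an unadjusted p under 0.05 there were 3329 genes.

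The largest rises were led by predicted or known proteases. CG17571 rose 198-fold, from 4.29 ± 0.62 to 11.92 ± 1.03 (adjusted p = 0.00598), and 160-fold to 299-fold with 1 array left out. Jon44E (CG8579) and CG11912, whose normal-diet means lay under log2 4, rose 74.0-fold and 57.5-fold with those means set to log2 4. These are not strict lower bounds, since normal-diet replicate 3 stood at 6.87 and 4.80. CG11911 rose by 5.94, CG10472 by 5.28 and Jon65Aii by 4.81. CG8562 and CG8560, both predicted carboxypeptidases, rose by 4.81 and 4.78. Npc2e (CG31410), of a family of sterol-binding proteins, rose 27.6-fold, from 7.70 ± 2.19 to 12.49 ± 0.39, or 11.8-fold without normal-diet replicate 2 and 50.3-fold without normal-diet replicate 3. CG31041 and Ag5r2 (CG9540) rose by 4.95 and 4.83. The fitted folds of all 12 of these largest rises, without the limit at log2 4, moved more than 1.5 times when 1 array was left out. The figure of 57.5-fold for CG11912 went from 43.9-fold to 69.2-fold as restricted-diet arrays were left out. The largest falls were smaller. phu (CG8147) fell by 2.45, from 9.14 ± 0.28 to 6.69 ± 0.53, and CG8112 fell from 9.35 ± 0.03 to 7.35 ± 0.15 (adjusted p = 9.11e-05). The cuticle protein genes Cpr11B (CG2555) and Cpr72Ec fell by 1.92 and 1.28, and CG13947 fell by 1.75. Nmdmc (CG18466), a mitochondrial enzyme of folate metabolism, fell by 1.60 and Nepl4, a neprilysin-like peptidase, by 1.33. jeb, a secreted ligand of the Alk receptor, fell by 1.32 and Dscam2, a neuronal adhesion molecule, by 1.18. CG42337, CG10383 and CG2993 fell by 1.42, 1.28 and 1.23.

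Digestive proteases had the largest median change of the 36 lists. Of 24 digestive proteases, 14 rose, none fell and 10 did not pass; adjusted over the list alone, 19 rose and 1 fell. Their median change was 1.56, or 1.30 with 4 members at their bound (camera adjusted p = 1.33e-10, adjusted p = 0.457 with an estimated correlation). Jon66Ci (CG7118) rose at least 3.60-fold, or 2.28-fold without restricted-diet replicate 1, while Jon74E and Jon65Aiii, already near the top of the scale, rose by 0.34 and 0.33. The protease mean of normal-diet replicate 2 was 7.97, the lowest of the 9 arrays. Of 11 midgut markers, a list added later, 3 rose (mesh, Tsp2A and Ssk) and 1 fell (Mip), with a median of 0.69. Of 16 sugar-digesting enzymes, 4 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell (median 0.51, camera adjusted p = 0.00570, adjusted p = 0.523 with an estimated correlation). The maltase Mal-A4 rose 10.1-fold, or 5.77-fold without normal-diet replicate 2. Mal-A1, another maltase, rose by 0.95 and tobi, an alpha-glucosidase, by 1.06, while Mal-B2 fell by 0.36.

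**Figure D1:**
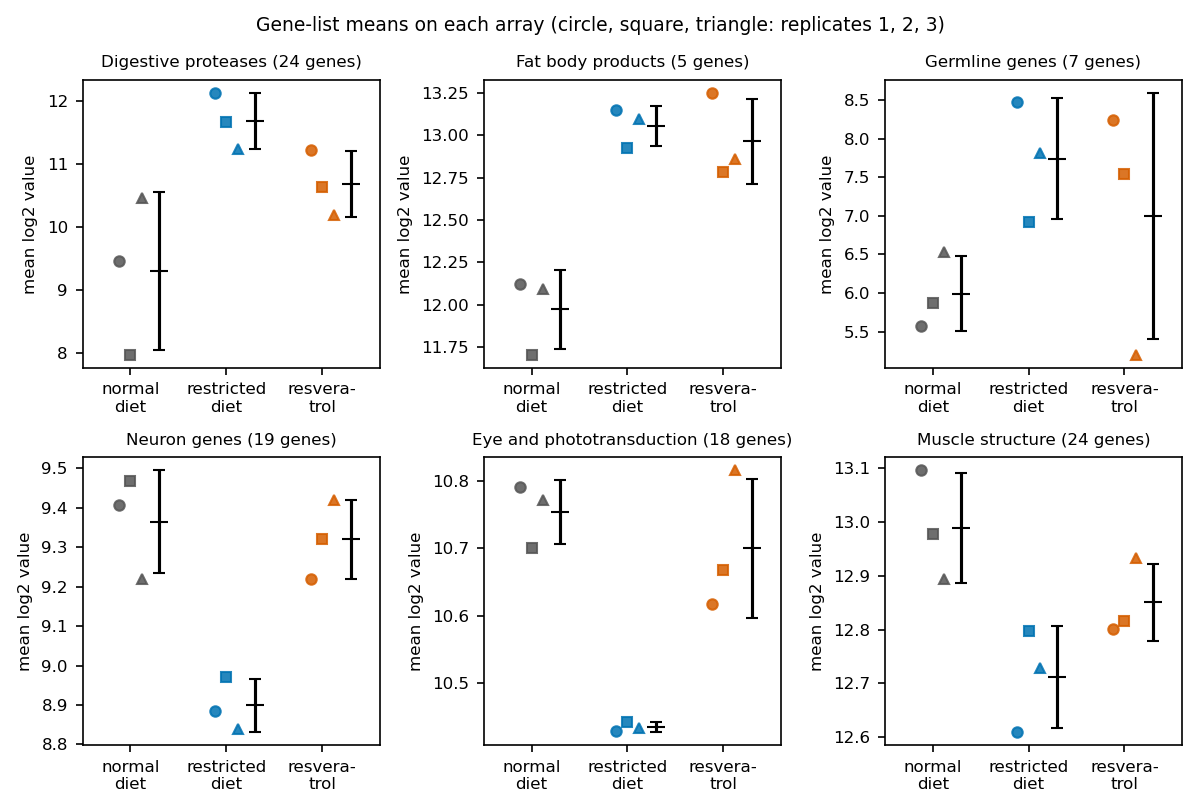
Mean log2 value of 6 gene lists on each of the 9 arrays, by diet. Points are single arrays and black bars the mean ± SD of 3 arrays; the eye list had a mean of 10.43 on the restricted diet against 10.75 on the normal diet, and the germline list spread from 5.199 to 8.244 within the resveratrol arrays.

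Fat body and lipid genes rose in part. Of 5 fat body products, 3 rose (fit by 0.78, Lsp2 by 3.89 and Obp99b, which the odorant-binding list also holds, by 1.39), and 3 rose adjusted over the list alone. The median was 0.78 (camera adjusted p = 0.0240, adjusted p = 0.457 with an estimated correlation). CG5966, a predicted lipase, did not pass (-0.63, adjusted p = 0.132), and without normal-diet replicate 2 the list's call ended. Of 18 lipid synthesis genes, 3 rose and 1 fell, against 5 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.00223, adjusted p = 0.457 with an estimated correlation). Dgat2 (CG1942), a diacylglycerol acyltransferase, rose 6.27-fold, from 5.04 ± 0.67 to 7.69 ± 0.29. Agpat2 and Men, malic enzyme, rose by 0.60 and 0.39, and SREBP, a transcriptional activator of lipid synthesis, fell by 0.32. Of 24 genes of lipid storage and breakdown, 4 rose and 3 fell, and adjusted over the list alone 10 rose and 3 fell. Their median was 0.02 (camera adjusted p = 0.0457, adjusted p = 0.457 with an estimated correlation). Beside Npc2e, Acox57D-p rose by 0.61, while Npc1a and the lipase Lip4 fell by 0.43 and 0.44.

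Most members of the neuron and eye lists fell, as did some of the glial and muscle lists. Of 19 neuron genes, 14 fell, none rose and 5 did not pass, and 15 fell adjusted over the list alone (median -0.46, camera adjusted p = 2.35e-06, adjusted p = 0.457 with an estimated correlation). The RNA-binding protein elav, the active-zone protein brp and the GABA receptor Rdl fell by 0.53, 0.41 and 0.46. Of 18 eye and phototransduction genes, 14 fell and 4 did not pass; adjusted over the list alone, 16 fell and 1 rose (median -0.47, camera adjusted p = 9.63e-07, adjusted p = 0.457 with an estimated correlation). Galphaq, trpl and Gbeta76C fell by 0.45, 0.50 and 0.38. Of 11 antennal genes, a list added later, 1 fell and 10 had negative changes, with a median of -0.29. Of 10 glial genes, 3 fell and 5 fell adjusted over the list alone (median -0.25, camera adjusted p = 0.0240, adjusted p = 0.523 with an estimated correlation). They were nrv2 (-0.52), the glial identity factor repo (-0.45) and the trehalose transporter Tret1-1 (-0.31); moody did not pass (-0.22, adjusted p = 0.0654). Of 24 muscle structure genes, 10 fell, and 13 fell adjusted over the list alone (median -0.27, camera adjusted p = 5.39e-05, adjusted p = 0.523 with an estimated correlation). Zasp52, the troponins TpnC4 and TpnC41C, and tn fell by 0.44, 0.66, 0.42 and 0.41.

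Some members of the clock and autophagy lists fell. Of 11 circadian clock genes, 6 fell, also adjusted over the list alone (median -0.35, camera adjusted p = 0.0340, adjusted p = 0.457 with an estimated correlation). They included vri (-0.66), Pdp1 (-0.59), tim (-0.53) and cwo (-0.38), and the list's call ended without resveratrol replicate 3. Of 22 autophagy genes, 5 fell, also adjusted over the list alone (median -0.15, camera adjusted p = 0.0240, adjusted p = 0.457 with an estimated correlation). Atg18b, Atg17, Atg8a and Atg12 fell by 0.56, 0.37, 0.23 and 0.21.

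Some members of the detoxification and proteasome lists rose. Of 29 glutathione transferases, 7 rose, and adjusted over the list alone 8 rose and 1 fell (median 0.10, camera adjusted p = 0.00931, adjusted p = 0.457 with an estimated correlation). GstE3 rose 2.41-fold, and GstE5, GstO3 and GstE9 rose by 0.68, 0.51 and 0.41. Of 22 UDP-glycosyltransferases, 3 rose and 7 rose adjusted over the list alone (median 0.27, camera adjusted p = 0.00574, adjusted p = 0.518 with an estimated correlation). They were Ugt37A2 (1.44), Ugt37D1 (0.63) and Ugt49B1 (0.40), while Ugt317A1 did not pass (0.57, adjusted p = 0.0563). Of 63 cytochrome P450 genes, 11 rose and 4 fell, against 11 and 6 adjusted over the list alone (median 0.02, camera adjusted p = 0.0255, adjusted p = 0.541 with an estimated correlation). Cyp6a14 rose 3.10-fold and Cyp12d1-d at least 1.27-fold, while Cyp9b1 and Cyp12a5 fell by 0.72 and 0.35. Of 22 antioxidant genes, 4 rose and 3 fell, against 6 and 4 adjusted over the list alone (median 0.10, camera adjusted p = 0.0499, adjusted p = 0.513 with an estimated correlation). MsrA, a methionine sulfoxide reductase, rose 3.10-fold, Prx6c and Keap1 rose by 0.82 and 0.54, and the metallothionein MtnA fell by 0.89. The antioxidant call held in 6 of 18 other settings. Of 26 proteasome subunits all had positive changes, 8 rose, and 9 rose adjusted over the list alone (median 0.20, camera adjusted p = 8.05e-08, adjusted p = 0.518 with an estimated correlation). Rpn11, Prosalpha6, Prosbeta6 and Prosalpha4 rose by 0.40, 0.39, 0.36 and 0.34.

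On the restricted diet camera called 21 lists at its preset correlation and 0 with an estimated correlation. Limma's fry called 14 lists, of which 10 were among those 21. It did not call the sugar digestion, lipid storage, P450, UDP-glycosyltransferase, antioxidant or proteasome lists (fry adjusted p from 0.0606 to 0.473). Nor did fry call 5 lists typical of growing and germline cells that camera called. In these 5 no single member passed except among mitochondrial ribosomal proteins. Germline transcripts, a list of 7 added later, had a mean of 5.99 ± 0.49 on the normal diet, 7.74 ± 0.78 on the restricted diet and 6.997 ± 1.596 with resveratrol (SD, n = 3). For 18 DNA replication genes the median was 0.99 and the camera adjusted p = 5.39e-05 (adjusted p = 0.523 with an estimated correlation); PCNA had a change of 1.82 (adjusted p = 0.0579), CycE 1.72 (3.30-fold, or 2.14-fold without normal-diet replicate 1), Mcm6 0.95 and PolD2 0.33. For 19 ovary and eggshell genes the median was 1.13 and the camera adjusted p = 0.00397 (adjusted p = 0.541 with an estimated correlation); aub had 2.17, piwi 1.88 and ovo 0.47, and orb stood at 7.53 and 9.54. For 30 ribosome biogenesis genes the median was 0.23 and the camera adjusted p = 0.000860 (adjusted p = 0.541 with an estimated correlation); Rrp1 had 0.88, mbm 0.59, Rrp46 0.40 and Nnp-1 0.34. For 30 cytosolic ribosomal proteins the median was 0.05 and the camera adjusted p = 0.00588 (adjusted p = 0.541 with an estimated correlation); RpS5b had 2.01 (adjusted p = 0.0973), RpL34a 0.15, RpLP2 0.13 and RpL40 0.07. In these 4 lists 0 members passed, also adjusted over the list alone, in limma. Of 71 mitochondrial ribosomal proteins, 1 rose and 2 fell, against 0 and 1 adjusted over the list alone (median 0.03, camera adjusted p = 0.0425, adjusted p = 0.660 with an estimated correlation). mRpL15 rose by 0.30, mRpS7 and mRpS30 fell by 0.26 and 0.23, and mRpS5 did not pass (-0.27, adjusted p = 0.0504).

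Camera did not call 15 lists (camera adjusted p from 0.0730 to 0.934). Of these, fry called insulin, TOR and FOXO genes lower (fry adjusted p = 0.0158) and sirtuin, p53 and AMPK genes lower (fry adjusted p = 0.00896). It also called the glycolysis list, which holds some glycogen genes too, lower (fry adjusted p = 0.0202) and yolk proteins higher (fry adjusted p = 0.0159). Insulin, TOR and FOXO genes had single changes. Of 19, Ilp5 rose by 0.53, and InR, the insulin receptor, fell by 0.90, its substrate chico by 0.43, foxo by 0.34 and scyl, a TOR inhibitor, by 0.31. Adjusted over the list alone 2 rose and 5 fell (median -0.14, camera adjusted p = 0.155). Of 13 sirtuin, p53 and AMPK genes, SNF4Agamma, a subunit of AMPK, and Naam, a nicotinamidase, fell by 0.24 and 0.51, and 2 fell adjusted over the list alone (camera adjusted p = 0.254). Sirt1 was at 10.93 ± 0.10 and 10.85 ± 0.01 (SD, n = 3; adjusted p = 0.376) and p53 at 8.01 ± 0.03 and 8.07 ± 0.19 (adjusted p = 0.745); Sirt4 and Sirt2 had changes of -0.29 and -0.15 and did not pass. Of 3 yolk proteins 1 passed, Yp2, and 2 adjusted over the list alone, in the higher direction. Yp1 stood at the ceiling on all 9 arrays, and Yp2 and Yp3 within 0.1 of it on 4 and 5, so no size of change is given for them. Of 12 takeout and juvenile hormone genes, the epoxide hydrolase Jheh2 rose by 0.94, Jhbp2 and Jhbp15 fell by 0.50 and 0.52, and Jhe did not pass (-0.81, adjusted p = 0.0950). The counts were the same adjusted over the list alone. The takeout list's median was -0.04, and the median of 4 antimicrobial peptides was -0.78, where camera's direction was upward for both. The median of 27 odorant-binding genes was -0.03 and their mean 0.12, with camera's direction upward.

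For 3952 of the 8822 genes, 44.8%, the 3 values of each diet did not overlap, where chance gives 10% on average. Genes vary together between arrays, so a share by chance can lie far from 10%, and its spread was not computed. The count of 1604 fell to 340 without normal-diet replicate 1, 501 without normal-diet replicate 2, 517 without restricted-diet replicate 1, 731 without restricted-diet replicate 3 and 1051 without resveratrol replicate 2; 284 of the 1604 genes passed under all 9 such fits. With the germline mean as a covariate, chosen after seeing the data, 6 genes passed, and all 1604 kept their sign. Their median absolute change went from 0.45 to 0.35 and the median SE from 0.09 to 0.10. The fit had 5 residual degrees of freedom, and 40.5% of the variance of the germline mean lay between diets. The covariate can therefore also take out part of an effect of diet.

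**Figure D2:**
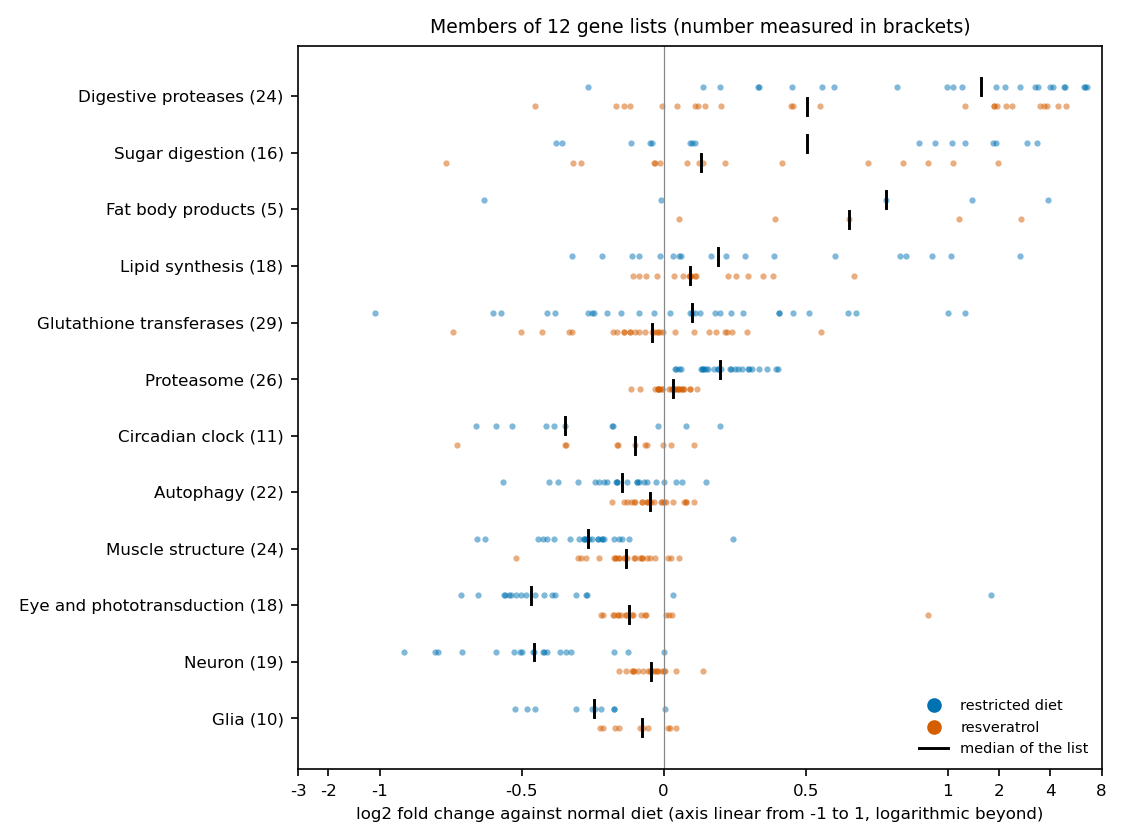
Log2 fold change of each measured member of 12 gene lists against the normal diet, on the restricted diet (blue) and with resveratrol (orange); black marks are list medians, and the axis is linear from -1 to 1 and logarithmic beyond. Digestive proteases had medians of 1.56 and 0.50, and neuron genes -0.46 and -0.04.

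Resveratrol was set against the normal diet to ask what the compound changes when added to that diet. It changed 20 genes in limma, 4 higher and 16 lower, against 859 at an unadjusted p under 0.05. The predicted serine protease CG11912 rose from 3.56 ± 1.08 to 8.87 ± 1.26 (SD, n = 3). With the normal-diet mean set to log2 4 this was 29.2-fold, or 17.8-fold without resveratrol replicate 1. It is not a strict lower bound, since normal-diet replicate 3 stood at 4.80. CG5246, another predicted serine protease, rose 8.61-fold, from 5.64 ± 0.27 to 8.74 ± 0.63. CG14219, under log2 4 on all 3 normal-diet arrays, rose at least 4.55-fold to 6.19 ± 0.42 (adjusted p = 0.00283). phu fell by 2.33, from 9.14 ± 0.28 to 6.81 ± 0.16, and CG13947 fell by 2.32, from 14.23 ± 0.54 to 11.91 ± 0.25.

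CG11741 fell by 1.99 and CG8112 by 1.08. Kr-h1 (CG45074), a transcription factor of the juvenile hormone response, fell by 0.98, hry (CG6494), the repressor hairy, by 0.85, and the clock repressor cwo (CG17100) by 0.73. CG12310 fell by 0.76, MFS14, of a family of membrane transporters, by 0.76, MtnA (CG9470) by 0.68, Pisd, phosphatidylserine decarboxylase, by 0.53, and CG3036 by 0.50. pn (CG3461), the phosphodiesterase prune, rose by 0.33. CG4820 and CG5707, named after their values were seen, fell by 0.44 and 0.49.

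Of 36 lists, 11 were called, 7 higher and 4 lower, with 0 of 36 called by camera at an estimated correlation and 1 by fry. The members of these lists did not pass over all genes tested, except cwo. Of 5 fat body products all had positive changes and 3 rose adjusted over the list alone (median 0.65, camera adjusted p = 8.24e-05, adjusted p = 0.134 with an estimated correlation); fit had 0.65 (adjusted p = 0.0662), Lsp2 2.69 (6.44-fold, or 3.97-fold without resveratrol replicate 1), Obp99b 1.17 and CG5966 0.39. Fat body products were the list that fry called (adjusted p = 0.000873). Of 24 digestive proteases 0 rose adjusted over the list alone (median 0.50, or 0.45 with 4 members at their bound, camera adjusted p = 4.10e-05, adjusted p = 0.712 with an estimated correlation); Jon25Biii had 4.95 (30.8-fold, or 13.9-fold without normal-diet replicate 2) and etaTry 1.27, and Jon44E did not pass (adjusted p = 0.467). Of 27 odorant-binding genes 7 rose adjusted over the list alone (median 0.05, camera adjusted p = 0.000730, adjusted p = 0.684 with an estimated correlation); Obp99a had 0.97, Obp56h 0.75, Obp49a 0.40 and Obp56d 0.20. Of 18 lipid synthesis genes 3 rose adjusted over the list alone (median 0.09, camera adjusted p = 0.00408, adjusted p = 0.419 with an estimated correlation); Agpat2 had 0.67 (adjusted p = 0.0626), mino 0.35 and Men 0.30. Of 24 lipid storage genes 3 rose and 2 fell adjusted over the list alone (median 0.11, camera adjusted p = 0.00163, adjusted p = 0.419 with an estimated correlation); Npc2e had 3.71 (13.1-fold, or 5.596-fold without normal-diet replicate 2), the lipase bmm 0.31, and Lip4 and Npc2h -0.39 each.

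The median of 19 ovary and eggshell genes was 0.85, or 0.84 with 2 members at their bound (camera adjusted p = 0.00279, adjusted p = 0.767 with an estimated correlation), and the chorion genes Cp36 and Cp38 had changes of 3.32 and 3.30 with adjusted p = 0.514 and 0.460 (10.0-fold and 9.88-fold, or 5.19-fold and 5.34-fold without normal-diet replicate 1). The median of 30 ribosome biogenesis genes was 0.12 (camera adjusted p = 0.0197, adjusted p = 0.767 with an estimated correlation), with Nop17l at 0.33 (adjusted p = 0.0753) and 1 member higher adjusted over the list alone. The germline mean was 6.997 ± 1.596 with resveratrol against 5.99 ± 0.49 on the normal diet (SD, n = 3). The list calls of ovary and of ribosome biogenesis ended without normal-diet replicate 1 or resveratrol replicate 1. Among lists called lower, the median of 24 muscle genes was -0.13 (camera adjusted p = 4.10e-05, adjusted p = 0.712 with an estimated correlation) and that of 18 eye genes -0.12 (camera adjusted p = 0.00163, adjusted p = 0.684 with an estimated correlation). TpnC41C had -0.29, Mlc1 -0.23, Galphaq -0.22 and Arr2 -0.16. For 56 respiratory chain genes the median was -0.05 (camera adjusted p = 0.00959, adjusted p = 0.767 with an estimated correlation), with COX7AL2 at -0.17. In these 3 lists 0 members passed adjusted over the list alone. Of 11 clock genes cwo fell, also adjusted over the list alone (median -0.10, camera adjusted p = 0.00959, adjusted p = 0.530 with an estimated correlation), and vri and Clk had -0.35 and -0.34.

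Of the lists named whatever their call, none was called for resveratrol. Among 13 sirtuin, p53 and AMPK genes 0 passed, also adjusted over the list alone (median -0.05, camera adjusted p = 0.154). Sirt1 had a change of -0.05 (adjusted p = 0.828) and p53 of -0.29 (adjusted p = 0.476). Among 19 insulin, TOR and FOXO genes 0 passed, and adjusted over the list alone 1 was higher and 2 lower (camera adjusted p = 0.908). Ilp5 had 0.63 (adjusted p = 0.0883), scyl -0.31 (adjusted p = 0.0972), daw -0.44 and foxo 0.02. That list's median was 0.01 with camera's direction downward. Of the yolk proteins, at or near the ceiling, 0 passed, also adjusted over the list alone (camera adjusted p = 0.209), and Jheh2 had 0.70 (adjusted p = 0.341). The values of the groups did not overlap for 1362 genes, 15.4%, where chance gives 10% on average, with a spread that was not computed. The count of 20 lay between 2 and 9 whichever of the 9 arrays was left out: 5, 9 and 5 without normal-diet replicates 1, 2 and 3, 9, 7 and 6 without restricted-diet replicates 1, 2 and 3, and 2, 3 and 5 without resveratrol replicates 1, 2 and 3. It was 4 with only the 6 arrays compared, 10 with no filter, 47 with trend and robust options and 269 with array weights, and the replicate-left-out fits kept 2 of the 20 genes throughout.

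Whether both treatments move the same transcripts was asked by setting their changes against the same normal-diet arrays. In limma 14 genes passed in both and all moved the same way, 4 higher and 10 lower. CG14219 was at least 8.38-fold higher on the restricted diet and at least 4.55-fold higher with resveratrol. With its normal-diet mean set to log2 4, CG11912 rose 57.5-fold and 29.2-fold, the latter 17.8-fold without resveratrol replicate 1. CG5246 rose by 3.23 and 3.11. Lower in both were phu (-2.45 and -2.33), CG13947 (-1.75 and -2.32), MtnA (-0.89 and -0.68), cdi (CG6027), a protein kinase (-0.78 and -0.40), CG12310 (-0.72 and -0.76) and cwo (-0.38 and -0.73). CG8112 fell from 9.35 to 7.35 on the restricted diet and to 8.27 with resveratrol.

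Independent lists of these sizes would share 0.211 genes higher and 2.07 lower, and 0 genes passed in opposite directions. The comparisons share their normal-diet arrays, so the lists are not independent and these figures are not chance levels. In each of 100 simulated sets of unchanged groups 0 genes passed the same way in both. Those sets held no real changes, so they give no chance level for the overlap either. Across 8822 genes, which are not independent replicates, the changes correlated at r = 0.810 and rho = 0.609. Simulated unchanged groups against the same controls gave a mean r of 0.514, with 95% of 100 simulations between -0.368 and 0.939, so r alone lay within that range. The covariance was 0.162 against a simulated mean of 0.0334 (0.128 above it), with 95% of simulations between -0.0145 and 0.117 and the highest at 0.194. The share of genes with the same sign was 72.4% against 68.6%, within the range of 40.3% to 88.0%. With separate normal-diet arrays for the 2 treatments, 1 against 2 in all 6 ways, a check chosen after seeing the data, r was 0.262 to 0.694 (mean 0.534) and the covariance 0.0481 to 0.185 (mean 0.123). Unchanged groups simulated in that way gave means of r between -0.674 and 0.628 and of the covariance between -0.0630 and 0.0790 in 95% of 100 simulations, with the highest covariance at 0.191. The same-sign share was 50.3% to 72.1%. The count of 14 fell to between 2 and 7 without any 1 array: 4, 7 and 4 without normal-diet replicates 1, 2 and 3, 4, 6 and 4 without restricted-diet replicates 1, 2 and 3, and 2, 3 and 4 without resveratrol replicates 1, 2 and 3.

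**Figure D3:**
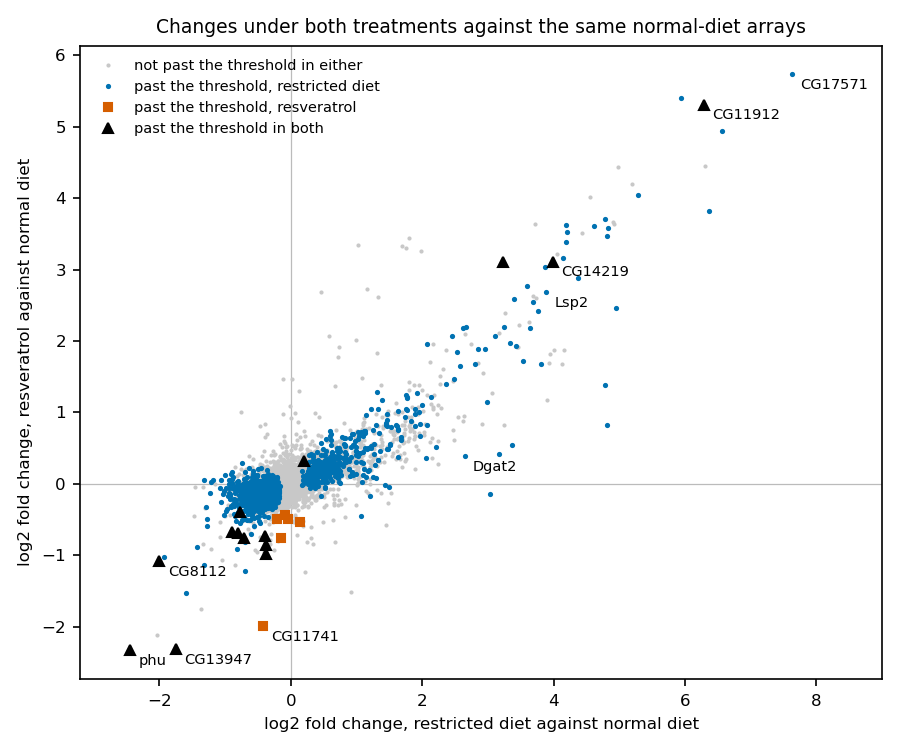
Log2 fold change of each of 8822 genes on the restricted diet (horizontal) and with resveratrol (vertical), both against the same 3 normal-diet arrays, colored by which comparison passed. The 14 genes past the threshold in both (black triangles) lie toward the lower left and the upper right.

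The restricted diet was set against resveratrol to test directly where the treatments differ. Some neuron and eye transcripts were lower on the restricted diet than with resveratrol, and Dgat2 and some Jonah proteases were higher. Dgat2 was 4.80-fold higher, at 7.69 ± 0.29 against 5.42 ± 0.51 (SD, n = 3). Dscam2 was lower by 1.23 (change -1.23), at 4.86 ± 0.09 against 6.08 ± 0.24. In limma 224 genes passed, 40 higher and 184 lower on the restricted diet, and 191 of them also passed for restricted diet against normal diet. The resveratrol mean lay between the others for 117 genes, beyond the normal-diet mean for 99 and beyond the restricted-diet mean for 8.

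Among the largest differences, Jon66Ci was at least 3.60-fold higher on the restricted diet (2.28-fold without restricted-diet replicate 1), and Jon25Bi, CG11741, CG13659 and Fancl, a ubiquitin ligase of DNA repair, were higher by 1.52, 1.56, 1.45 and 1.30. The nuclear receptor Hr38 (CG1864) had a change of -1.23, and CG1979 was at least 1.74-fold higher with resveratrol. The transcription factor kn, Axs and CG5644 had changes of -1.12, -1.12 and -1.06.

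Of 36 lists, 13 were called, 10 higher and 3 lower, with 0 by camera at an estimated correlation and 4 by fry. Of fry's calls 3 were among the 13. The other was autophagy, lower on the restricted diet (fry adjusted p = 0.0150), which camera did not call (camera adjusted p = 0.0902). Of 19 neuron genes 7 were lower, and 15 adjusted over the list alone (median -0.39, camera adjusted p = 1.70e-07, adjusted p = 0.687 with an estimated correlation); the sodium channel para had -1.05, VAChT -0.78, elav -0.42 and brp -0.40. Of 18 eye genes 6 were lower, and 13 adjusted over the list alone (median -0.32, camera adjusted p = 9.46e-07, adjusted p = 0.647 with an estimated correlation); inaC had -0.58, inaE -0.53, trp -0.48 and ninaB -0.41. Of 24 muscle genes 0 passed, also adjusted over the list alone (median -0.13, camera adjusted p = 0.0218, adjusted p = 0.819 with an estimated correlation); Zasp52 had -0.28. Of 24 digestive proteases 2 were higher, Jon25Bi and Jon66Ci, and 4 adjusted over the list alone (median 0.66, camera adjusted p = 2.62e-07, adjusted p = 0.687 with an estimated correlation). Of 26 proteasome subunits 0 passed and 6 were higher adjusted over the list alone (median 0.17, camera adjusted p = 3.69e-09, adjusted p = 0.687 with an estimated correlation); Prosbeta6 had 0.30 (adjusted p = 0.0599). Of 29 glutathione transferases GstE5 and GstE3 were higher by 0.57 and 0.72; adjusted over the list alone 7 were higher and 1 lower (median 0.13, camera adjusted p = 6.33e-05, adjusted p = 0.647 with an estimated correlation). Of 22 antioxidant genes MsrA was higher by 1.26, and 2 were higher adjusted over the list alone (median 0.11, camera adjusted p = 0.00579, adjusted p = 0.647 with an estimated correlation).

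The median of 16 sugar-digesting enzymes was 0.37 (camera adjusted p = 0.00813, adjusted p = 0.779 with an estimated correlation), with Mal-A1 at 0.83, and that of 18 replication genes 0.68 (camera adjusted p = 0.000143, adjusted p = 0.779 with an estimated correlation), with PCNA at 1.09. Much of the latter rested on resveratrol replicate 3, without which the replication median was 0.19 (camera adjusted p = 0.0284) and PCNA went from 2.13-fold to 1.32-fold. The median of 71 mitochondrial ribosomal proteins was 0.04 (camera adjusted p = 0.0214, adjusted p = 0.819 with an estimated correlation), with mRpL4 at 0.19. In these 3 lists 0 members passed, also adjusted over the list alone. The germline mean was 7.74 ± 0.78 on the restricted diet and 6.997 ± 1.596 with resveratrol (SD, n = 3). Of 30 ribosome biogenesis genes Nop17l was lower (-0.32), also adjusted over the list alone (median 0.07, camera adjusted p = 0.0322, adjusted p = 0.819 with an estimated correlation). Of 22 UDP-glycosyltransferases 0 passed and 3 were higher adjusted over the list alone (median 0.10, camera adjusted p = 0.0322, adjusted p = 0.779 with an estimated correlation), with Ugt37A2 at 1.46 (adjusted p = 0.0619). Of 27 amino acid metabolism genes 0 passed, and adjusted over the list alone 1 was higher and 1 lower (median 0.06, camera adjusted p = 0.0386, adjusted p = 0.687 with an estimated correlation), with Gnmt, glycine N-methyltransferase, at 2.12 (adjusted p = 0.0533).

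Outside the called lists, chico and foxo were lower on the restricted diet than with resveratrol (-0.40 and -0.36), the members of 19 insulin, TOR and FOXO genes that passed, also adjusted over the list alone (camera adjusted p = 0.158). Jhbp2 and Jhbp15 were lower (-0.39 and -0.63), again also adjusted over the list alone. Of 13 sirtuin, p53 and AMPK genes 0 passed and 2 were lower adjusted over the list alone; p53 had 0.35 (adjusted p = 0.125), Sirt1 -0.02 and Naam -0.43 (adjusted p = 0.0723). Of the yolk proteins, at or near the ceiling, 0 passed, also adjusted over the list alone (camera adjusted p = 0.222). For 19 ovary genes the median was 0.20 and the mean -0.03. The values did not overlap for 2738 genes, 31.0%, where chance gives 10% on average, with a spread that was not computed. The smallest adjusted p was 0.0255, and the count of 224 moved to 4 without normal-diet replicate 1, to 6, 44 and 0 without restricted-diet replicates 1, 2 and 3, and to 0 without resveratrol replicate 2 or replicate 3 (2219 genes at an unadjusted p under 0.05 with all arrays). It was 36 after quantile normalization and 21 after median centring, where the share lower went from 82.1% to 44.4% and 33.3%, and 1 with only the 6 arrays compared.

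Signs of RNA quality were compared between the diets through control probe sets for the 3' end, middle and 5' end of transcripts. The 3' minus 5' difference of eIF-4a was 2.76 ± 0.11 on the normal diet, 2.72 ± 0.16 on the restricted diet and 2.72 ± 0.01 with resveratrol (SD, n = 3), and that of GAPDH 0.65 ± 0.03, 0.70 ± 0.11 and 0.74 ± 0.03. For 18S rRNA it was 0.79 ± 0.12, 0.30 ± 0.22 and 0.77 ± 0.15, a change of -0.49 on the restricted diet (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give; adjusted p = 0.48 over 24 comparisons). Actin moved the other way between its 3' end and middle: that difference was -0.45 on the normal diet and -0.12 on each of the others, a change of 0.33 on the restricted diet (two-sided exact permutation p = 0.1, adjusted p = 0.48) and 0.33 with resveratrol (exact permutation p = 0.2, adjusted p = 0.686). Its 3' minus 5' difference changed by -0.12 on the restricted diet (exact permutation p = 0.5) and 0.00876 with resveratrol (exact permutation p = 1).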

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

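The alternatives below were fixed before the data were examined, except the germline covariate, the separate normal-diet arrays for the 2 treatments and the leave-outs of the RNA quality measure, which were chosen only after seeing the results. Each diet had 3 arrays, so counts of genes rest on few values, and the count for restricted diet against normal diet kept its direction under every alternative but a minimum of 2-fold, where higher genes prevailed, and the germline covariate. Of the named genes that passed, 47 of 100 on the restricted diet, 1 of 17 with resveratrol and 0 of 28 between the treatments passed in all 21 settings, and none changed sign. Labels number the replicates alike in each diet but name no shared batch, so the numbers were not taken as pairs in the main fit, as set beforehand. In a check on the data, the deviations of arrays sharing a number correlated from -0.33 to 0.40. The causes of the differences between settings were not tested.

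For restricted diet against normal diet the count of 1604 genes was 598 with no filter, 1017 without moderation, 931 with a replicate block, 152 at 2-fold or more, 2747 at an adjusted p under 0.1 and 6 with the germline covariate. Leaving out each array in turn gave 340 to 1670. For resveratrol against normal diet the count of 20 was 10 with no filter, 4 with only the 6 arrays compared, 47 with trend and robust, 269 with array weights, 9 without moderation, 1 with a replicate block, 7 at 2-fold or more, 61 at an adjusted p under 0.1 and 11 with the germline covariate. Leaving out each array gave 2 to 9. For restricted diet against resveratrol the count of 224 was 36 after quantile normalization, 21 after median centring, 8 with no filter, 1 with only the 6 arrays compared, 339 with trend and robust, 1340 with array weights, 7 without moderation, 0 with a replicate block, 23 at 2-fold or more, 884 at an adjusted p under 0.1 and 46 with the germline covariate. Leaving out each array gave 0 to 289.

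The count of 14 genes changed the same way in both treatments was 6 with no filter, 3 with only the 6 arrays compared, 39 with trend and robust, 176 with array weights, 6 without moderation, 1 with a replicate block, 6 at 2-fold or more, 50 at an adjusted p under 0.1 and 2 with the germline covariate. Leaving out each array gave 2 to 7. With separate normal-diet arrays the correlation of the changes, 0.810 with shared ones, was 0.262 to 0.694, and the covariance, 0.162 with shared ones, 0.0481 to 0.185.

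With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons, against 21, 11 and 13 at the preset correlation, and fry called 14, 1 and 4. With no filter 17 lists were called for resveratrol. Leaving out each array gave 18 to 21 lists for the restricted diet, 8 to 17 for resveratrol and 10 to 14 between the treatments. On the restricted diet the call of the P450 list held in 11 of 18 other settings, that of lipid storage in 9 and that of mitochondrial ribosomal proteins in 12, and the call of cytosolic ribosomal proteins ended after quantile normalization. Between the treatments amino acid metabolism held in 9, ribosome biogenesis in 11, and UDP-glycosyltransferases in 12. The eIF-4a difference between restricted and normal diet, 3' minus 5', was -0.04 and went from -0.13 to 0.03 over the leave-outs.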

Other observations

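Apart from the splits, the tests below, the marker lists they use and the single genes named in this paragraph were chosen only after seeing the results, and of these tests only the midgut prediction was written before its own value was known. PGRP-SC2, a secreted peptidoglycan amidase that dampens immune signaling in the gut, rose by 2.08 on the restricted diet (adjusted p = 0.00125) and was higher by 1.25 than with resveratrol (adjusted p = 0.0276); of the 24 immune recognition and signaling genes in its list it alone rose and 2 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.872). Gnmt, glycine N-methyltransferase, rose by 3.81 (adjusted p = 0.00648) and Sam-S, which makes S-adenosylmethionine, by 0.23, while the amino acid metabolism list was not called (camera adjusted p = 0.112). Taldo and Rpi, enzymes of the pentose phosphate pathway, for which no list was tested, rose by 0.63 and 0.59. Of 15 genes in the glycolysis list 4 fell, also adjusted over the list alone, and 4 had positive changes. Those that fell were Hex-A and Pfk (by 0.37 and 0.28), glycogen synthase Glys (by 0.38) and glycogen phosphorylase Glyp (by 0.22). Glys and Glyp are genes of glycogen metabolism and not of glycolysis itself. Camera did not call the glycolysis list (camera adjusted p = 0.219), while fry called it lower (fry adjusted p = 0.0202). Slob, which binds the potassium channel Slowpoke, fell by 0.76 (adjusted p = 0.00598) and was lower than with resveratrol (-0.70).

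Antimicrobial peptides varied between arrays of the same diet. Their mean was highest on normal-diet replicate 2, at 13.38, and next on restricted-diet replicate 1, at 12.14, and Drs reached 14.38 on the former. The 4 genes did not vary alike: Mtk also stood at 13.88 on normal-diet replicate 3, and Def at 10.75 on resveratrol replicate 1. On the same normal-diet array the protease mean was lowest, 7.97, and Jon99Fi stood at 2.17 against 9.23 and 12.03 on the other normal-diet arrays. CG4440 and CG13427 stood at 8.76 and 8.85 on restricted-diet replicate 2, 6.35 and 6.87 on restricted-diet replicate 3 and 8.89 and 8.33 on resveratrol replicate 2, and at or near the lowest value on the other 6 arrays.

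The rise of digestive proteases could reflect regulation in the gut or more midgut tissue in the restricted-diet samples. Midgut markers had a median change of 0.6895 (95% -0.10 to 0.79). The bound was 0.78, which is 0.5 of the protease median, or 0.65 with members at their bound, so the test could not tell. The marker list was mixed. The junction genes mesh, Tsp2A and Ssk rose by 0.69, 0.79 and 0.73. Beside them the list held transcription factor genes (cad, fkh, nub and esg) and the neuropeptide gene Mip. Mip, Cad87A and fkh had negative changes, of -0.36, -0.19 and -0.10. The 95% intervals in this and the next paragraph come from resampling the genes of a list, not the arrays. They therefore leave out the spread between arrays. Carry-over of midgut and ovary together could not be told either: within diets the protease and germline means correlated at r = 0.4902 over 9 arrays (two-sided exact permutation p = 0.0972, adjusted p = 0.0972 over 2 relations, rho = 0.567, exact permutation p = 0.111), and r = 0.386 without the 2 farthest arrays. The array with the fewest protease transcripts, normal-diet replicate 2, did not carry the whole median change. Without it the median was 1.234, above 0.78, though 6 of 24 genes then passed. Camera at its preset correlation still called the list (adjusted p = 9.71e-11). With an estimated correlation it did not call the list even with all arrays (adjusted p = 0.457).

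The fall of neuron and eye genes could reflect lower expression in the same tissue or a smaller share of head. Antennal genes, which mark the head, could not tell, with a median change of -0.2863 (95% -0.41 to -0.13, which spans the bound of -0.23). No test was set for whether a larger share of carried-over tissue lowered these genes. With the germline mean as a covariate the neuron median went from -0.46 to -0.30 and the eye median from -0.47 to -0.37. Of the variance of that covariate 40.5% lay between diets, so the fit cannot separate carry-over from an effect of diet. Less head against thorax would not lower muscle genes, which are largely thoracic, yet their median was -0.27 (95% over genes -0.30 to -0.22) and 23 of 24 had negative changes. Camera did not call the muscle list with an estimated correlation (adjusted p = 0.523). Median centring left the neuron median at -0.4527 but moved the median over all genes by only 0.0052, so it could not test scaling of the arrays. Lower RNA integrity stays open: of 6 differences of the eIF-4a, GAPDH and actin controls 4 were negative, but that of actin between its 3' end and middle was 0.329, over the bound of 0.2. Against it, that actin difference was also 0.331 with resveratrol, where the neuron median was -0.04 and the list was not called (camera adjusted p = 0.323). The 18S rRNA difference, -0.49 on the restricted diet, was not among the controls of this test and is not read either way.

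The spread of ovary and replication genes between arrays of the same diet fits varying carry-over of ovary into the head and thorax samples. Within diets the germline and replication means correlated at r = 0.871 over 9 arrays (two-sided exact permutation p = 0.0324, adjusted p = 0.0648 over 2 relations). Spearman's rho was 0.75 (exact permutation p = 0.0787), and r was 0.672 without the 2 farthest arrays, so part of the relation rests on them. With the germline mean as a covariate the list medians on the restricted diet moved. They went from 1.56 to 1.32 for proteases, from -0.46 to -0.30 for neurons and from -0.47 to -0.37 for eye. For fat body the median went from 0.78 to 0.80 and for muscle from -0.27 to -0.13.

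For each comparison, 1 of 10 splits of the 6 arrays, the real split, gave as many genes as were found (1604, 20 and 224), and the highest other counts were 0, 0 and 3. The splits are too few for a share under 0.05.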
